A study of Mus musculus with 4 samples.

How the data were processed

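RNA from the ventricles of newborn mice at postnatal day 1 was extracted with Trizol, and 1.5 µg of total RNA and 20 ng of polyA RNA went into each stranded Kapa library, per the labels' protocols. The 4 libraries were 2 controls with floxed Ctnnb1 and no Cre and 2 knockout-labelled libraries with floxed Ctnnb1 and alphaMHC-Cre. The read length and the release of the gene annotation are not given in the sources used here.

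Reads were demultiplexed with bcl2fastq 2.16.0.10, checked with FastQC 0.11.5, aligned to GRCm38 with STAR 2.5.3a and counted per gene with HTSeq 0.6.1, per the submitters' processing notes. The deposited counts are whole numbers of reads per gene with no scaling. The series table repeats the same counts in 4 columns, which were equal to the per-sample files, and gives the authors' log2 fold changes of knockout over control. Its p-values and adjusted p-values were deposited by the authors, whose processing notes name DESeq2, with a contrast and settings that the notes do not state. Of its other 14 columns, 4 hold normalized values per sample, and none of these was used here. The authors' log2 fold changes and adjusted p-values served only for the count of shared calls and for Ctnnb1, whose deposited log2 fold change was 0.25 (adjusted p = 0.495 with DESeq2).

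The files hold 53465 genes, of which 53274 were matched by identifier to GENCODE vM21 on GRCm38 for symbols, types and positions. The 5 HTSeq summary categories were kept out of library sizes and tests. Reads assigned to more than 1 place made up 19.4%, 21.0%, 23.9% and 29.7% of all counted reads in controls 1 and 2 and knockout-labelled libraries 1 and 2, reads outside genes 6.06%, 6.45%, 4.38% and 3.18%, and ambiguous reads 4.85%, 4.43%, 4.28% and 3.90%. All counted reads numbered 62138349, 65490456, 67703658 and 53839729 in the same order. A count of 0 allows up to 0.0693, 0.0672, 0.0657 and 0.0882 CPM in these libraries, the level at which 3 reads would be expected. These floors were taken from library totals, without TMM scaling. Replicates of a group differed by far more than counting error, with a chi-square per degree of freedom of 50.2 over 20461 genes in the controls and 119 over 19313 genes in the knockout-labelled libraries. Intervals on shares of reads cover counting error only.

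Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults, which left 18157, and libraries were scaled by TMM, with factors of 1.08, 1.10, 0.972 and 0.869. Groups were compared with the quasi-likelihood test without further covariates, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. CPM values other than the floors for a count of 0 are TMM-scaled. In this text ± after a mean of CPM is the SD of 2 libraries and ± after a log2 fold change is its SE. The smallest adjusted p above the threshold, 0.0925, was shared by 616 genes. In a test on simulated data of the same size with 100 genes changed at each of 2 sizes, edgeR recovered 21% of the 2-fold and 81% of the 4-fold changes with 8 false among 110 calls, DESeq2 45% and 95% with 49 false among 189, and limma-voom 18% and 80% with 9 false among 107. The simulation, in which genes were independent, also shifted 1 list, which camera called with the preset and with an estimated correlation, and 0 of 27 others were called with the preset. It does not test lists whose members vary together. Genes in the recovery test varied only by their fitted dispersions, with no trends shared across a library, such as that with GC content. The recovered shares therefore need not hold for these data.

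Before the data were examined, 28 gene lists were fixed from general knowledge: Wnt targets and feedback genes, adherens junction and intercalated disc, cell cycle, glycolysis and lactate, pyruvate dehydrogenase and tricarboxylic acid cycle, fatty acid and ketone use, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, mitochondrial biogenesis, fetal and stress genes, sarcomere, calcium handling, integrated stress response, hypoxia, p53, interferon response, extracellular matrix, immediate-early genes, 9 lists of cell type markers and sex-linked genes. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation and with fry, adjusted over the 28 lists. Members were also adjusted over their list alone. The test, scaling, filter and most alternatives were likewise chosen before the data were examined. Genes to be named were Ctnnb1, the largest and the most abundant changes past the threshold apart from pseudogenes and unnamed genes, of which there were 0, and from each list up to 4 members past the threshold over all genes or else the member with the smallest p, which gave 27 entries. Both called pseudogenes, which this rule skips, and a further 38 genes were chosen after their values were seen, among the latter Axin2, Mki67, Oxct1, Nppb, Irf7 and Tfrc.

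The alternatives were DESeq2's size factors, scaling by library totals alone, no filter, a stricter filter of 1 CPM in 2 libraries, removal of mitochondrial and haemoglobin genes, a replicate block, each library left out in turn, DESeq2 1.42.0, limma-voom and a log2 fold change of at least 1. After the data were examined, removal of trends with GC content and transcript length, protein-coding genes only, a crossed block and alternatives within DESeq2 were added. The trends were splines with 4 degrees of freedom per library, fitted on nuclear protein-coding genes and removed from 18135 genes. On simulated data the removal took a GC trend from a rho of -0.67 to -0.01. Across 14547 genes, which are not independent, the log2 fold change had a Spearman rho of -0.35 with GC content and -0.13 with length, and 0.01 and -0.04 after removal. The length trend lay in knockout-labelled 2. Its median deviation from the control mean in log2(CPM + 1) was 0.16 in the fifth with the shortest genes and -0.25 in the longest. In knockout-labelled 1 these medians were -0.01 and 0.03. Scaling by library totals alone shifted log2 fold changes by a median of -0.24. Processed pseudogenes were aligned to protein-coding transcripts with blastn 2.17.0, and 1099 of 1107 had a closest transcript, 1091 with its gene tested. Results of some single genes are not reported.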

Results

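RNA was sequenced from the ventricles of newborn mice at postnatal day 1. The 4 libraries formed 2 groups of 2 by their titles and genotypes. Knockout-labelled mice carried floxed alleles of Ctnnb1 and an alphaMHC-Cre transgene, which drives the Cre recombinase in cardiomyocytes, and control mice carried the floxed alleles without Cre. The comparison therefore takes in the presence of the transgene as well as the deletion. Ctnnb1 encodes β-catenin, a protein of cell-cell junctions and the transcriptional co-activator of canonical Wnt signalling, and the series title names energy metabolism and mitochondrial function as the subject. Control libraries 1 and 2 held 43288936 and 44624578 counts in genes, and knockout-labelled libraries 1 and 2 held 45651797 and 34027143. Between 25017 and 27801 genes had at least 1 count. Nothing in the labels says that the samples are separate animals, so p-values here measure only the spread between these samples.

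Libraries of the same group resembled each other more closely than most pairs of different groups. Across genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.987 between the controls and 0.981 between the knockout-labelled libraries. Between groups it ranged from 0.963 to 0.982, the highest value being that of control 2 with knockout-labelled 1. The first principal component held 60.7% of the variance and placed the controls at -40.8 and -24.5 and the knockout-labelled libraries at 19.6 and 45.7. Single libraries stood apart in a few genes. Xist, the RNA that coats the inactive X chromosome, was at 0.257, 0.327 and 0.180 CPM in control 1, control 2 and knockout-labelled 1 and at 602 CPM in knockout-labelled 2. Kdm5d, a Y-linked gene, was at 41.3, 42.4 and 37.4 CPM in the same 3 libraries. Its count of 0 in knockout-labelled 2 allows up to 0.0882 CPM before TMM scaling. Together these give a female pattern in that library and a male one in the other 3. Trbc2, a T-cell receptor constant gene, was at 46.2 CPM in control 1 and at most 0.797 CPM elsewhere. Mitochondrially encoded genes took 5.25% and 7.65% of the gene counts in controls 1 and 2 and 10.2% and 14.4% in knockout-labelled libraries 1 and 2.

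The targeted gene was not lower in the knockout-labelled libraries. Ctnnb1 (ENSMUSG00000006932), on the forward strand of chromosome 9 from 120929216 to 120960507 in GRCm38, was at 409 and 434 CPM in controls 1 and 2 and at 527 and 460 CPM in knockout-labelled libraries 1 and 2. The group means were 421 ± 18.1 and 493 ± 46.9 CPM (SD, n = 2 each), and the log2 fold change was 0.23 ± 0.20 (SE; adjusted p = 0.532, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With scaling by library totals alone the value was -0.0086 (adjusted p = 0.984 in edgeR, within a range of 0.341 to 0.984 over the alternatives tried). The count covers the whole gene, so it takes in exons outside any deleted part and transcripts of non-myocytes, and the labels do not name the deleted exons. It therefore does not check the labels, and every direction given here is that of the libraries labelled knockout.

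The only genes to pass over all genes were processed pseudogenes. Over all 18157 genes tested, edgeR's quasi-likelihood test called 2 genes higher and 0 lower in the knockout-labelled libraries at an adjusted p under 0.05, and both were processed pseudogenes of Rplp0, a ribosomal protein gene. Gm8730, on chromosome 8 from 102864845 to 102865798, rose from 8.47 and 6.81 CPM in controls 1 and 2 to 147 and 236 CPM in knockout-labelled libraries 1 and 2, a log2 fold change of 4.65 ± 0.31 (SE; adjusted p = 0.0472 in edgeR). Gm9625, on chromosome 13 from 67810246 to 67811200, rose from 5.41 ± 0.509 to 56.7 ± 11.1 CPM (SD, n = 2 each), a log2 fold change of 3.39 ± 0.22 (SE; adjusted p = 0.0472 in edgeR). Their closest protein-coding transcripts were those of Rplp0, at 98.7% and 97.4% identity, so their reads are easily exchanged and both values are uncertain, and Rplp0 itself had a log2 fold change of -0.40 ± 0.26 (SE; adjusted p = 0.391 in edgeR). Processed pseudogenes as a class had a median log2 fold change of 1.31 over 1107 tested genes, against -0.03 over 14565 protein-coding genes. The size depends on how low counts are treated. In log2(CPM + 1), processed pseudogenes lay above the control mean by medians of 0.42 and 0.46 in knockout-labelled libraries 1 and 2. They took 0.193% and 0.182% of the gene counts in the controls and 0.339% and 0.359% in the knockout-labelled libraries, where the share of reads assigned to more than 1 place was also higher (19.4% and 21.0% against 23.9% and 29.7%). Neither pseudogene passed when control 1, control 2 or knockout-labelled 2 was left out, while edgeR called 0 genes higher and 30 lower without control 2 and 9 higher and 6 lower without knockout-labelled 1.

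**Figure D1:**
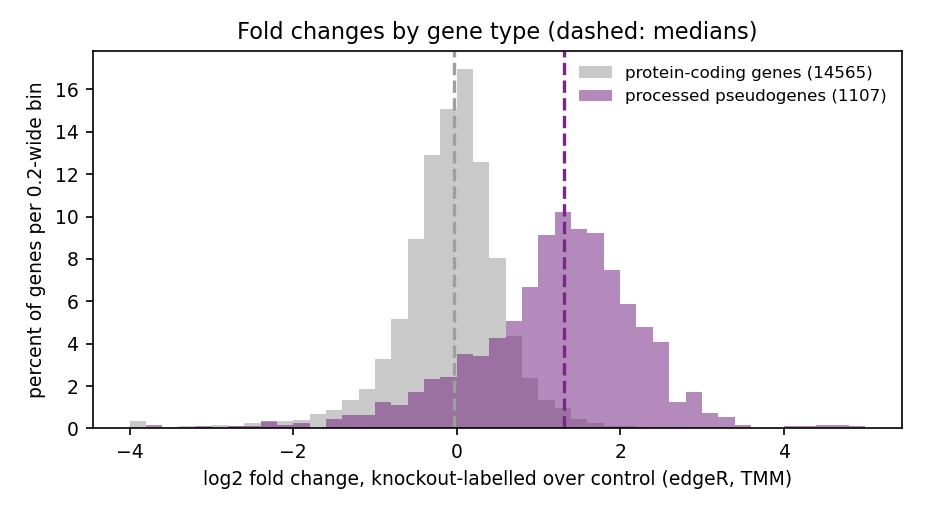
Log2 fold changes of the knockout-labelled over the control libraries (x axis; edgeR, TMM scaling, values outside the range drawn at its ends) as the percent of genes per bin (y axis) for 14565 protein-coding genes and 1107 processed pseudogenes. Dashed lines mark the medians, -0.03 and 1.31.

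At an unadjusted p under 0.05 edgeR had 2137 genes higher and 2039 lower, where 908 in all would be expected by chance, and at an adjusted p under 0.1 it had 513 higher and 389 lower. With no filter on low counts it called 313 higher and 241 lower at an adjusted p under 0.05. DESeq2 called 951 higher and 755 lower of 17034 genes with an adjusted p, and limma-voom called 0 in either direction, with 2087 higher and 1948 lower at an unadjusted p under 0.05. Among protein-coding genes DESeq2 called 638 higher and 657 lower, and among processed pseudogenes 270 higher and 4 lower. Both knockout-labelled libraries lay above both controls for 4810 genes and below both for 5395, 56.2% of those tested, where chance gives 16.7% per direction. The authors' deposited table listed 959 genes higher and 759 lower at an adjusted p under 0.05, and 1700 of these were called in the same direction by DESeq2 here. Leaving out control 1 reduced DESeq2's counts to 104 higher and 53 lower, and leaving out control 2 to 197 and 324. Without knockout-labelled 2 DESeq2 called 575 higher and 583 lower. As edgeR called only these 2 pseudogenes over all genes, 0 members of the 28 gene lists passed there, and the members of each list that rose or fell are those with an edgeR p adjusted over the list alone.

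**Figure D2:**
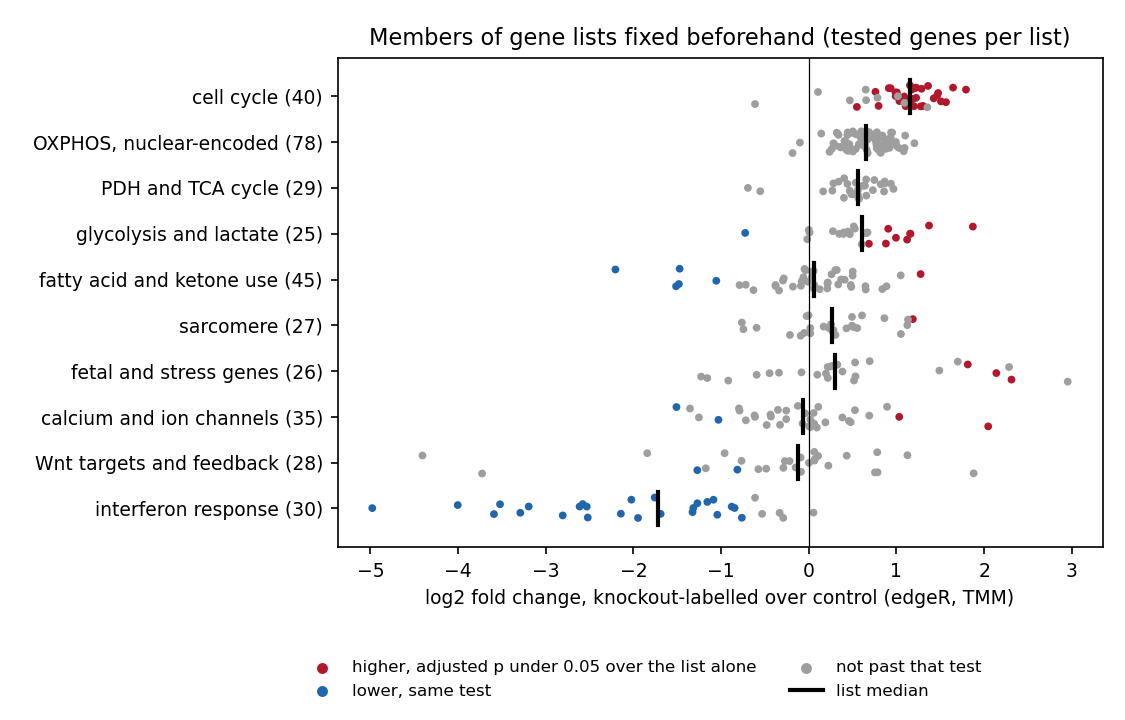
Log2 fold change (x axis; edgeR, TMM scaling) of each tested member of 10 gene lists, given by row with the number of tested members. Red and blue points passed an adjusted p under 0.05 over the list alone and black bars are list medians, which ran from -1.72 for the interferon response to 1.15 for the cell cycle.

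Few Wnt target genes passed. Of 28 tested targets and feedback genes of Wnt/β-catenin signalling, 2 fell and 0 rose when adjusted over the list alone (edgeR; 0 over all genes, with 5 higher and 6 lower at an unadjusted p under 0.05), and DESeq2 called 4 lower and 1 higher. Lgr6, an R-spondin receptor on chromosome 1 from 134983301 to 135105276, fell from 35.2 ± 5.29 to 14.6 ± 3.85 CPM (SD, n = 2 each), a log2 fold change of -1.27 ± 0.25 (SE). Bambi, a pseudoreceptor that dampens TGF-β signalling, fell from 40.1 ± 1.39 to 22.8 ± 0.974 CPM, a log2 fold change of -0.81 ± 0.16. Both had an adjusted p of 0.0308 over the list alone (edgeR). Axin2, a direct target used widely as a readout of the pathway, was at 5.53 and 6.62 CPM in the controls and at 2.35 and 3.04 CPM in the knockout-labelled libraries (fitted ratio 0.443, adjusted p = 0.0703 over the list alone, edgeR). The list's median log2 fold change was -0.12 (-0.21 without control 1, -0.20 without knockout-labelled 1, -0.06 after GC content and length trends were removed and -0.36 with library totals alone), and camera, limma's competitive test of gene lists, did not set it apart (adjusted p = 0.326). Without control 1 or without knockout-labelled 2 the number of members passing was 0, and without knockout-labelled 1 it was 4 higher and 5 lower. The transcription factors Lef1 and Tcf7 had log2 fold changes of -3.73 and -4.41 that rested on control 1, which also held the T-cell transcripts, and were -0.74 and -0.75 without it.

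Proliferation genes rose together. Of 40 tested cell cycle genes, 31 rose and 0 fell when adjusted over the list alone (edgeR; 0 over all genes, with 32 higher and 0 lower at an unadjusted p under 0.05), and DESeq2 called 24 of them higher. Rrm2, the ribonucleotide reductase subunit needed for DNA synthesis (chromosome 12, 24708241 to 24714146), rose from 14.2 ± 3.05 to 49.2 ± 0.141 CPM (SD, n = 2 each), a log2 fold change of 1.79 ± 0.21 (SE; adjusted p = 0.00499 over the list alone, edgeR). Mki67, the proliferation marker (chromosome 7, 135689784 to 135716361), rose from 74.6 ± 20.0 to 160 ± 10.5 CPM, and Top2a, the topoisomerase of dividing cells, from 46.1 ± 13.1 to 105 ± 17.2 CPM, each with an adjusted p of 0.0171 over the list alone (edgeR). The median log2 fold change of the list was 1.15, and camera placed it higher than other genes (adjusted p = 1.13e-15; adjusted p = 0.657 with an estimated correlation). The list's median was 0.916 without control 1, 1.397 without control 2, 1.390 without knockout-labelled 1 and 0.998 without knockout-labelled 2. Each of these fits leaves 1 library in a group, so only the size of the change is given. With scaling by library totals alone the median was 0.892 and 17 members rose.

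Some glycolysis and lactate transport genes rose. Of 25 tested, 9 rose and 1 fell when adjusted over the list alone (edgeR; 0 over all genes, with 13 higher and 1 lower at an unadjusted p under 0.05), and DESeq2 also called 9 higher and 1 lower. Slc16a3, the lactate exporter MCT4 (chromosome 11, 120948480 to 120960868), rose from 7.65 ± 0.127 to 28.0 ± 9.61 CPM (SD, n = 2 each), a log2 fold change of 1.87 ± 0.29 (SE; adjusted p = 0.00767 over the list alone, edgeR). The glycolytic enzyme Pgk1 rose from 165 ± 10.2 to 367 ± 57.4 CPM and lactate dehydrogenase A, Ldha, from 526 ± 25.7 to 1049 ± 281 CPM. Pfkfb2, which sets the level of the phosphofructokinase activator, was the member that fell, by a log2 fold change of -0.73 ± 0.19. Camera placed the list higher (median 0.60, adjusted p = 4.42e-07; adjusted p = 0.657 with an estimated correlation), and the median was 0.39 without knockout-labelled 2 and 0.34 with library totals alone. The members passing were 0 without either control, 16 higher and 1 lower without knockout-labelled 1, 4 higher and 1 lower with library totals alone, and 15 higher and 1 lower after GC content and length trends were removed.

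No gene of pyruvate oxidation or the tricarboxylic acid cycle passed singly in edgeR. Of 29 tested, 25 lay higher in both knockout-labelled libraries than in both controls, and 2 lay lower in both, against a chance share of 16.7% per direction for a single gene and 4810 higher of the 18157 genes tested. These members vary together (estimated correlation between members 0.352), so their number does not test the list, and 0 passed when adjusted over the list alone (edgeR; 18 higher and 1 lower at an unadjusted p under 0.05). DESeq2 called 13 higher and 0 lower. The median log2 fold change was 0.56, and camera placed the list higher (adjusted p = 3.86e-08; adjusted p = 0.657 with an estimated correlation). Dld, the dihydrolipoamide dehydrogenase shared by the pyruvate and 2-oxoglutarate complexes, was at 242 ± 7.92 CPM in the controls and 472 ± 8.15 CPM in the knockout-labelled libraries (SD, n = 2 each), with a log2 fold change of 0.97 ± 0.18 (SE; adjusted p = 0.0534 over the list alone, edgeR) that was 0.59 after GC content and length trends were removed. Without knockout-labelled 1 the members passing were 17, with DESeq2's size factors they were 8, and with library totals alone the list's median was 0.31.

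Of 78 tested subunits of the respiratory chain encoded in the nucleus, 63 lay higher in both knockout-labelled libraries and 0 lay lower in both. Chance gives 16.7% for a single gene and 4810 of all 18157 genes lay higher, but members of this list vary together (estimated correlation between members 0.816), so their number does not test the list. The median log2 fold change was 0.66 and camera placed the list higher (adjusted p = 9.13e-16; adjusted p = 0.657 with an estimated correlation). Adjusted over the list alone 0 members passed (edgeR; 42 higher and 0 lower at an unadjusted p under 0.05), and DESeq2 called 29 higher. Cycs, cytochrome c, was at 284 and 256 CPM in the controls and at 483 and 760 CPM in the knockout-labelled libraries, a log2 fold change of 1.20 ± 0.27 (SE; adjusted p = 0.0735 over the list alone, edgeR) that was 0.80 after GC content and length trends were removed. Without knockout-labelled 1 the members passing were 68, and the list's median was 0.96 without that library, 0.38 without knockout-labelled 2 and 0.40 with library totals alone.

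Most mitochondrially encoded subunits rose. Of 13, 10 rose and 0 fell when adjusted over the list alone (edgeR; 0 over all genes, with 11 higher at an unadjusted p under 0.05), and DESeq2 called 11 higher. The complex I subunits mt-Nd1 and mt-Nd2, at positions 2751 to 3707 and 3914 to 4951 of the mitochondrial genome, had log2 fold changes of 1.83 ± 0.42 and 1.85 ± 0.39 (SE, n = 2 libraries per group) and adjusted p-values of 0.00898 and 0.00722 over the list alone (edgeR). After removal of GC content and length trends, which were fitted on nuclear genes only and carried over to these, the values were 1.05 and 1.06. Some members were barely detected: mt-Co3 had 7 and 12 counts in the controls and 304 and 317 in the knockout-labelled libraries, and since reads of this part of the genome can be shared with nuclear copies of mitochondrial DNA its value is uncertain. Camera placed the list higher (median 1.85, or 1.06 after that removal, adjusted p = 1.58e-10; adjusted p = 0.657 with an estimated correlation). The share of reads assigned to more than 1 place moved with these genes, from 19.4% and 21.0% in the controls to 23.9% and 29.7% in the knockout-labelled libraries. Without control 1 the members passing were 5.

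Fatty acid and ketone genes split. Of 45 tested, 5 fell and 1 rose when adjusted over the list alone (edgeR; 0 over all genes, with 5 higher and 8 lower at an unadjusted p under 0.05), and DESeq2 called 6 lower and 2 higher. Ucp3, a mitochondrial uncoupling protein (chromosome 7, 100472990 to 100486432), fell from 117 ± 3.87 to 40.8 ± 5.39 CPM (SD, n = 2 each), a log2 fold change of -1.51 ± 0.17 (SE; adjusted p = 0.00467 over the list alone, edgeR). Cpt1b, the muscle carnitine palmitoyltransferase that admits long-chain fatty acids to the mitochondrion, fell from 22.6 ± 2.55 to 8.12 ± 1.53 CPM. The fatty acid transporter Slc27a1 and the lipase inhibitor Angptl4 fell by 1.47 and 1.05 on the log2 scale. Oxct1, which starts the oxidation of ketone bodies (chromosome 15, 4026383 to 4155344), rose from 123 ± 12.6 to 299 ± 9.90 CPM, a log2 fold change of 1.28 ± 0.18 (adjusted p = 0.00467 over the list alone, edgeR). The list's median was 0.06, its mean -0.04 and its camera direction higher (adjusted p = 0.838), and the median was -0.20 with library totals alone and -0.04 without control 2. Without control 1, 0 of its members passed. They were 3 lower without control 2, 7 lower and 6 higher without knockout-labelled 1, and 8 lower and 1 higher with library totals alone.

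**Figure D3:**
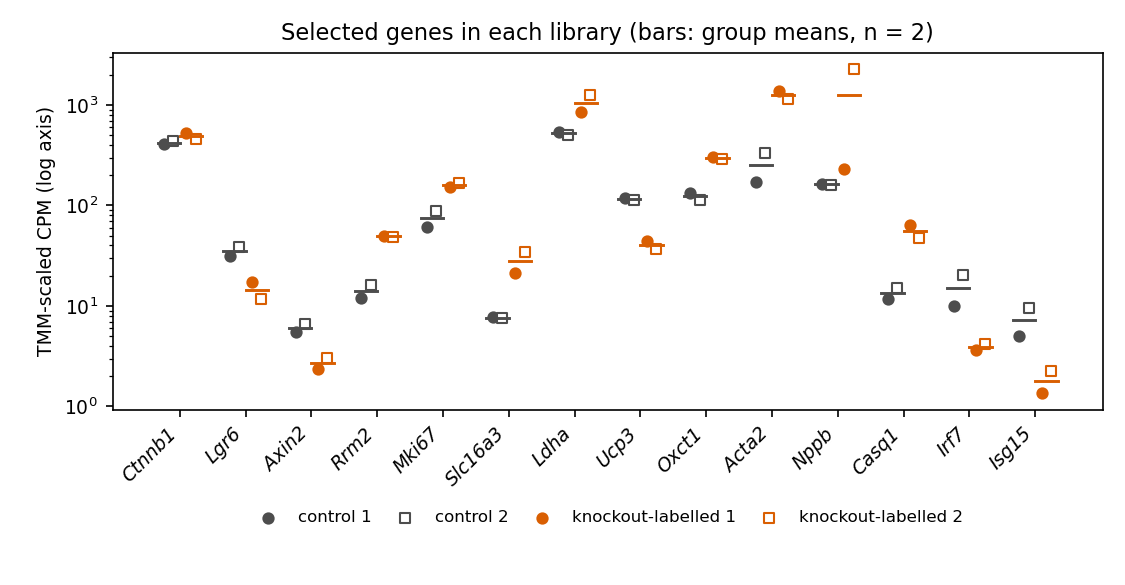
TMM-scaled CPM (log axis) of 14 genes in each of the 4 libraries, with bars at the group means (n = 2). Ctnnb1 lay between 409 and 527 CPM, Ucp3 had means of 117 and 40.8 CPM, and Nppb was high in knockout-labelled 2 alone at 2288 CPM.

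Among genes of mitochondrial biogenesis, dynamics and quality control, Ckmt2 alone passed. Of 43 tested, 1 rose and 0 fell when adjusted over the list alone (edgeR; 0 over all genes, with 14 higher and 3 lower at an unadjusted p under 0.05), and DESeq2 called 8 higher and 1 lower. Ckmt2, the mitochondrial creatine kinase of muscle, rose from 78.2 ± 2.24 to 194 ± 19.3 CPM (SD, n = 2 each), a log2 fold change of 1.31 ± 0.17 (SE; adjusted p = 0.0115 over the list alone, edgeR). Camera placed the list higher (median 0.29, or 0.06 with library totals alone, adjusted p = 0.00115; adjusted p = 0.657 with an estimated correlation). The members passing were 0 without either control, 17 higher and 1 lower without knockout-labelled 1, 4 higher without knockout-labelled 2 and 4 higher with DESeq2's size factors.

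Contractile genes that mark the fetal or stressed heart were higher for a few members. Of 26 tested, 3 rose and 0 fell when adjusted over the list alone (edgeR; 0 over all genes, with 7 higher and 1 lower at an unadjusted p under 0.05), and DESeq2 called 4 higher. Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590), rose from 253 ± 113 to 1256 ± 168 CPM (SD, n = 2 each), a log2 fold change of 2.31 ± 0.36 (SE). Acta1, skeletal actin, rose from 30.7 ± 11.9 to 108 ± 12.5 CPM, and the myosin light chain Myl9 from 314 ± 90.6 to 1382 ± 437 CPM. All 3 had an adjusted p of 0.00678 over the list alone (edgeR). Nppb, the natriuretic peptide released by strained myocardium, was at 164, 161 and 233 CPM in control 1, control 2 and knockout-labelled 1 and at 2288 CPM in knockout-labelled 2, and its log2 fold change of 2.95 was 0.53 without that library. Camera placed the list higher (adjusted p = 0.0230; adjusted p = 0.657 with an estimated correlation), a call that ended without knockout-labelled 2 (adjusted p = 0.218). Without control 1, 0 members passed, without knockout-labelled 1 they were 11 higher and 1 lower, and without knockout-labelled 2 they were 3 higher and 1 lower.

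In the list of 27 ventricular sarcomere genes 1 rose when adjusted over the list alone (edgeR; 0 over all genes, with 4 higher and 2 lower at an unadjusted p under 0.05), and DESeq2 called 5 higher and 2 lower. Smpx, a small costameric protein, rose from 246 ± 23.8 to 560 ± 101 CPM (SD, n = 2 each), with a log2 fold change of 1.19 ± 0.22 that was 0.79 after GC content and length trends were removed. Cardiac actin, Actc1, was at 6840 ± 867 and 14912 ± 1129 CPM, a log2 fold change of 1.12 ± 0.35 (SE; adjusted p = 0.0856 over the list alone, edgeR). Camera placed the list just past the threshold (adjusted p = 0.0497, or 0.657 with an estimated correlation). It did not pass with library totals alone (adjusted p = 0.0852) or the stricter filter (adjusted p = 0.0689). Camera's adjusted p was 0.0059 after removal of GC content and length trends and 0.0015 with no filter on low counts. The list's median of 0.27 was 0.19 without control 2 and 0.10 without knockout-labelled 2. It lay within the range of lists matched for GC content, length and level (0.06 to 0.33). Members that passed numbered 3 without knockout-labelled 1 and 0 when any other library was left out.

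Calcium handling and ion channel genes changed singly and in both directions. Of 35 tested, 2 rose and 2 fell when adjusted over the list alone (edgeR; 0 over all genes, with 5 higher and 4 lower at an unadjusted p under 0.05), and DESeq2 called 3 higher and 2 lower. The sarcoplasmic calcium buffers Casq1 (chromosome 1, 172209894 to 172219868) and Casq2 (chromosome 3, 102086415 to 102146514) rose by log2 fold changes of 2.05 ± 0.23 and 1.03 ± 0.22 (SE, n = 2 libraries per group), Casq1 from 13.4 ± 2.33 to 55.5 ± 11.2 CPM and Casq2 from 740 ± 17.2 to 1514 ± 6.19 CPM (SD). Kcnip2, a subunit of the transient outward potassium channel, fell from 142 ± 0.491 to 69.7 ± 4.73 CPM, a log2 fold change of -1.03 ± 0.16. Sln, sarcolipin, an inhibitor of the calcium pump, fell by 1.51 on the log2 scale, or by 0.97 without control 2. Camera did not set the list apart (adjusted p = 0.645), except without knockout-labelled 1 (adjusted p = 0.0282, lower). Members that passed numbered 1 higher and 1 lower without control 1, 1 higher without control 2, 3 higher and 10 lower without knockout-labelled 1 and 4 higher and 1 lower without knockout-labelled 2. Of 28 adherens junction and intercalated disc genes 0 passed (edgeR; 1 higher and 0 lower at an unadjusted p under 0.05, 1 higher with DESeq2), and Pdlim1, a cytoskeletal adaptor, had the smallest p, with a log2 fold change of 0.62 ± 0.17 (SE; adjusted p = 0.273 over the list alone, edgeR) that was 0.39 after GC content and length trends were removed and 0.37 with library totals alone. Camera's adjusted p for that list was 0.608, and 0.0410 without knockout-labelled 2.

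Most interferon-stimulated genes were lower. Of 30 tested, 25 fell and 0 rose when adjusted over the list alone (edgeR; 0 over all genes, with 25 lower at an unadjusted p under 0.05), and DESeq2 called 22 lower and 0 higher. The median log2 fold change was -1.72, and camera placed the list lower than other genes (adjusted p = 7.78e-11; adjusted p = 0.657 with an estimated correlation). Irf7, the transcription factor that amplifies the interferon response (chromosome 7, 141262706 to 141266481), fell from 15.1 ± 7.17 to 3.91 ± 0.398 CPM (SD, n = 2 each), a log2 fold change of -1.95 ± 0.39 (SE; adjusted p = 0.0138 over the list alone, edgeR). The ubiquitin-like modifier Isg15 fell from 7.32 ± 3.29 to 1.81 ± 0.645 CPM (adjusted p = 0.0157 over the list alone, edgeR). Of the immune cell markers, 7 of 11 lymphocyte genes, 0 of them without control 1, and 3 of 20 myeloid genes, among them Cd68 and Csf1r, also fell when adjusted over their lists alone (edgeR). The chemokine Cxcl10 had 107 and 176 counts in the controls and 6 and 7 in the knockout-labelled libraries. Without knockout-labelled 1, 2 members fell. Without control 2, 3 fell, the median was -1.09 and Irf7's value was -1.35.

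Among stress-related lists, camera placed 1 higher. Of 29 integrated stress response and serine synthesis genes 1 rose when adjusted over the list alone (edgeR; 0 over all genes, with 9 higher and 1 lower at an unadjusted p under 0.05), and DESeq2 called 7 higher. Psat1, an enzyme of serine synthesis, rose from 17.8 ± 2.04 to 37.3 ± 3.41 CPM (SD, n = 2 each), a log2 fold change of 1.06 ± 0.18 (SE; adjusted p = 0.0330 over the list alone, edgeR). Camera's adjusted p for the list was 0.0333 (adjusted p = 0.711 with an estimated correlation), but 0.637 without control 2 and 0.382 without knockout-labelled 2, and the median of 0.29 ranged from -0.04 without knockout-labelled 2 to 0.73 without control 1. Members that passed numbered 11 higher and 1 lower without knockout-labelled 1 and 0 without any 1 of the other 3 libraries. Of 21 hypoxia genes 1 fell, Mxi1, an antagonist of Myc (-0.80 ± 0.16, edgeR's adjusted p = 0.0428 over the list alone), and of 28 p53 target and apoptosis genes 1 rose, Ccng1, cyclin G1 (0.98 ± 0.17, or 0.59 after GC content and length trends were removed, edgeR's adjusted p = 0.0375 over the list alone). DESeq2 called 1 higher and 1 lower in the hypoxia list and 4 higher in the p53 list. Camera set neither list apart (adjusted p = 0.475 and 0.150), though both were placed higher without knockout-labelled 1 (adjusted p = 0.0141 and 0.00818) and the p53 list also without control 1 (adjusted p = 0.0381). Without knockout-labelled 1 the hypoxia list had 5 higher and 1 lower and the p53 list 6 higher, without either control both had 0, and without knockout-labelled 2 the p53 list had 1 higher and 1 lower.

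Extracellular matrix and immediate-early genes lay at the threshold of camera's test. Of 31 matrix genes 0 passed when adjusted over the list alone (edgeR; 2 higher and 0 lower at an unadjusted p under 0.05, 1 higher with DESeq2), and the list was placed higher (median 0.25, or -0.02 with library totals alone, adjusted p = 0.0488; adjusted p = 0.657 with an estimated correlation). That call ended without control 1 (adjusted p = 0.312) or knockout-labelled 2 (adjusted p = 0.167) with library totals alone (adjusted p = 0.0852) and with the stricter filter (adjusted p = 0.0594), and the median was 0.07 without control 1 and 0.42 without control 2. Camera's adjusted p for the matrix list was 0.00023 after removal of GC content and length trends and 0.0120 with no filter on low counts. Loxl2, a collagen cross-linking enzyme, had the smallest p, with a log2 fold change of 0.84 ± 0.20 (SE, adjusted p = 0.189 over the list alone, edgeR). Of 24 immediate-early genes 0 passed (edgeR; 1 higher and 4 lower at an unadjusted p under 0.05, 1 higher and 2 lower with DESeq2), and the list was placed lower (median -0.33, adjusted p = 0.0497; adjusted p = 0.657 with an estimated correlation). Without knockout-labelled 1 camera's adjusted p was 0.979 and without control 2 it was 0.171, and after removal of GC content and length trends it was 0.261. It was 0.0949 with library totals alone, 0.0592 with the stricter filter, 0.0509 without mitochondrial and haemoglobin genes and 0.0595 with protein-coding genes only. The median was -0.07 without knockout-labelled 1 and -0.63 without knockout-labelled 2. Jun, a component of the AP-1 transcription factor, had the smallest p, with a log2 fold change of -0.61 ± 0.16 (SE; adjusted p = 0.0786 over the list alone, edgeR). Leaving out knockout-labelled 1 gave 5 higher matrix genes and 3 higher immediate-early genes, and leaving out knockout-labelled 2 gave 1 higher and 7 lower immediate-early genes.

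Markers of cells other than ventricular cardiomyocytes moved unevenly. Of 11 tested lymphocyte genes 7 fell when adjusted over the list alone (edgeR; 0 over all genes, with 8 lower at an unadjusted p under 0.05, 5 lower with DESeq2), but 0 passed without control 1, knockout-labelled 1 or knockout-labelled 2. Cd4 was at 36.8 CPM in control 1 and at 1.12, 0.135 and 0.372 CPM in control 2 and the knockout-labelled libraries 1 and 2. Camera placed the lymphocyte list lower (adjusted p = 0.00959, or 0.657 with an estimated correlation and 0.0852 with library totals alone). The lymphocyte median log2 fold change of -6.29 was -1.75 without control 1 and -5.60 without knockout-labelled 1, each fit with 1 library left in a group. Of 20 atrial and conduction system markers 2 fell, Sln and the transcription factor Tbx5 (59.1 and 81.0 CPM in the controls, 37.8 and 31.3 CPM in the knockout-labelled libraries), each with an adjusted p of 0.0300 over the list alone (edgeR; 0 over all genes, with 9 lower at an unadjusted p under 0.05, 4 lower with DESeq2). Camera placed the atrial list lower (median -0.92, adjusted p = 0.000235; adjusted p = 0.657 with an estimated correlation), but not without control 2 (adjusted p = 0.0628, median -0.49), where 0 members passed and Sln's log2 fold change of -1.51 was -0.97. The atrial members that fell were 6 without control 1, 7 without knockout-labelled 1, 1 without knockout-labelled 2 and 6 with library totals alone.

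Of 20 macrophage and myeloid genes 3 fell and 1 rose when adjusted over the list alone (edgeR; 0 over all genes, with 4 lower and 2 higher at an unadjusted p under 0.05, 3 lower and 1 higher with DESeq2). The lysosomal marker Cd68 fell from 13.1 ± 2.52 to 4.85 ± 0.166 CPM (SD, n = 2 each), Csf1r, the receptor that sustains macrophages, from 36.1 and 31.9 CPM to 21.7 and 19.8 CPM and the monocyte marker Ly6c2 from 1.11 ± 0.304 to 0.192 ± 0.0159 CPM, while the mannose receptor Mrc1 rose from 17.9 ± 0.462 to 34.9 ± 9.95 CPM. Of 15 smooth muscle and pericyte genes 4 fell, Notch3, Pdgfrb, Myh11 and Vtn, by 0.84, 0.57, 0.65 and 1.72 on the log2 scale, each with an adjusted p of 0.0438 over the list alone (edgeR; 6 lower and 1 higher at an unadjusted p under 0.05, 2 lower and 1 higher with DESeq2), and Acta2 was the member that rose. The values of Notch3, Pdgfrb, Myh11 and Csf1r were -0.44, -0.31, -0.42 and -0.46 after GC content and length trends were removed, where 0 smooth muscle genes fell. Camera set neither list apart (adjusted p = 0.133 and 0.145), although myeloid genes were placed lower without control 2 (adjusted p = 0.0157), without knockout-labelled 2 (adjusted p = 0.00478), after removal of GC content and length trends (adjusted p = 0.0136) and with no filter on low counts (adjusted p = 0.0432). Without control 1, 0 members of either list passed, and without control 2, 3 myeloid genes fell and 1 smooth muscle gene rose. Without knockout-labelled 2 the members passing were 0 of the myeloid list and 1 higher of the smooth muscle list, and without knockout-labelled 1 they were 5 higher and 4 lower and 2 higher and 5 lower. With library totals alone 9 myeloid and 6 smooth muscle genes fell.

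Fibroblast, endothelial and epicardial markers had 0 members passing over the list alone of 15, 20 and 14 tested (edgeR; 1, 4 and 0 lower and 0 higher at an unadjusted p under 0.05, 0 with DESeq2). Camera's adjusted p was 0.800, 0.388 and 0.325, and the endothelial list was placed lower only without knockout-labelled 2 (adjusted p = 0.00609). Their members with the smallest p were Fbln1, a matrix protein (-0.88 ± 0.30, SE, or -0.49 without control 2), Cldn5, an endothelial tight junction protein (-0.52 ± 0.16), and Upk1b (0.69 ± 0.29, or 0.43 both after GC content and length trends were removed and with library totals alone). Without knockout-labelled 1, 2 fibroblast and 4 endothelial genes were higher, and without knockout-labelled 2, 1 endothelial gene was lower. Of 12 erythroid genes 1 fell, the α-globin Hba-a2, from 72.6 ± 5.65 to 33.3 ± 1.62 CPM (SD, n = 2 each; edgeR's adjusted p = 0.00448 over the list alone, with 3 lower at an unadjusted p under 0.05, 2 lower with DESeq2), and haemoglobin genes took 0.114% and 0.119% of the gene counts in the controls and 0.0712% and 0.0549% in the knockout-labelled libraries. The erythroid median was -0.20, its mean 0.01 and its camera direction lower (adjusted p = 0.299), and the members passing were 0 without either control, 2 lower and 1 higher without knockout-labelled 1, where the median was 0.19, and 2 lower without knockout-labelled 2. Of 11 neuronal and Schwann cell genes 1 fell, Mbp, myelin basic protein, from 12.3 ± 1.51 to 4.89 ± 0.703 CPM (edgeR's adjusted p = 0.0264 over the list alone, with 2 lower and 1 higher at an unadjusted p under 0.05, 1 lower with DESeq2). Camera's adjusted p for it was 0.218, 0.00716 without control 1 and 0.0407 with no filter on low counts (lower in both), and the members passing were 2 without knockout-labelled 1 and 0 without any other library. Of 5 sex-linked genes 0 passed (edgeR; 1 higher at an unadjusted p under 0.05, 1 higher with DESeq2), with a median of -0.65, a mean of 1.37 that rests on Xist in knockout-labelled 2, and a camera direction lower (adjusted p = 0.178). Camera's adjusted p for them was 0.00657, 0.0298 and 0.0153 without control 1, control 2 and knockout-labelled 1, and 0.0407 with no filter on low counts. Without knockout-labelled 1 their members passing were 1 higher and 4 lower, and without knockout-labelled 2 their median was 0.22.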

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

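The tests of parent expression and strain variants were chosen after the pseudogene changes had been seen, and the test of read placement was written before its result was seen. The share of reads assigned to more than 1 place, a category outside the gene counts, was 23.9% in knockout-labelled 1 and 29.7% in knockout-labelled 2, above the 19.4% and 21.0% of the controls.

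Processed pseudogenes were higher in the knockout-labelled libraries, with a log2 fold change above 0 for 976 of 1107 and a median of 1.31. For 860 of the 1107 both knockout-labelled libraries lay above both controls, and for 66 both lay below. Expression of the parent genes does not account for all of this rise in these libraries. The pseudogenes exceeded their closest protein-coding genes by a median of 0.904 (95% bootstrap interval 0.851 to 0.968). Pseudogenes were resampled singly, although 1091 of them shared 610 closest genes, so the interval does not measure spread between samples. Parent expression may account for part of the rise, as those closest genes had a median of 0.31 over 610 genes, with 80.3% higher. Among all protein-coding genes 47.8% were higher. Strain variants acting singly were predicted to give changes in both directions, but 88.2% were higher (86.12 to 90.01, over genes that are not independent). This share cannot exclude strain differences that shift reads in a single direction, so strain background remains open. The change rose with identity to the closest transcript (Spearman's rho 0.226, 0.164 to 0.286, across genes that are not independent), and the median was -0.47 over 65 pseudogenes under 90% identity against 1.37 over 1034 others (a split chosen after the values were seen), which is consistent with reads placed differently by sequencing or alignment. Loss of Ctnnb1 or the Cre transgene was not tested as a cause and remains open.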

How the results depend on the processing

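Counts of genes and of lists moved with several choices, and the cause was not tested except where given. Of the values of named genes other than Ctnnb1 over the alternatives, 812 kept direction and side of the threshold, 105 kept direction and passed it, 8 kept direction and no longer passed, and 1 turned: Xist, -0.68 without knockout-labelled 2, which alone holds it, and 11.04 without knockout-labelled 1. Ctnnb1, uncalled throughout, turned to -0.0086 with library totals alone and 0.18 to 0.33 with single libraries left out. Against 2 genes higher and 0 lower in edgeR, there were 313 and 241 with no filter, 951 and 755 with DESeq2, and 0 and 0 with limma-voom. With protein-coding genes only there were 0 higher, since both called genes are pseudogenes. Leaving out single libraries gave 0 to 9 higher and 0 to 30 lower, and it leaves a group with 1 sample, assumed to vary like the other group. With library totals alone the genes at an unadjusted p under 0.05 were 1143 higher and 3706 lower, against 2137 and 2039.

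Against 10 lists higher and 4 lower, there were 8 and 2 with library totals alone, 10 and 7 with no filter, 8 and 2 with the stricter filter, and 7 to 12 and 4 to 6 with single libraries left out. With an estimated correlation there were 0 and 0 (smallest adjusted p = 0.657) and with fry 0 and 0 (smallest adjusted p = 0.334). In DESeq2, single libraries left out gave 104 to 1369 higher and 53 to 1085 lower, protein-coding genes only gave 711 and 626, and removal of GC content and length trends gave 750 and 667, of which 1088 were shared with the full run.

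The libraries share only a replicate number, and same-numbered deviations from the group means had a correlation of -0.14 across genes. The replicate block gave 9 genes higher and 9 lower in edgeR, 406 and 354 in DESeq2, and 9 lists higher and 3 lower, without sarcomere (adjusted p = 0.0756) and immediate-early genes (adjusted p = 0.0508). Crossed pairing gave 501 genes higher and 440 lower.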

Other observations

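The test of T-lineage transcripts and those of knockout-labelled 2 and of the cardiomyocyte share were chosen after their patterns had been seen, and that of GC content and length before. Outside the fixed lists, and chosen after their values were seen, 4 single genes differed in DESeq2's test. Tfrc, the transferrin receptor (chromosome 16, 32608920 to 32632794), rose from 72.1 ± 3.11 to 289 ± 49.3 CPM (SD, n = 2 each; DESeq2's adjusted p = 3.98e-16, edgeR's 0.0925, highest over the alternatives 0.615). Tap1, the peptide transporter of antigen presentation, fell from 13.3 ± 2.89 to 3.52 ± 0.190 CPM, a log2 fold change of -1.92 ± 0.28 (SE; DESeq2's adjusted p = 1.09e-06, edgeR's 0.0925, highest 0.615). Nlrc5, the activator of MHC class I genes, fell from 2.84 ± 0.319 to 0.135 ± 0.0956 CPM (DESeq2's adjusted p = 7.45e-07, edgeR's 0.0925, highest 0.615). Cd274, the immune checkpoint ligand PD-L1, fell from 4.67 ± 1.43 to 0.767 ± 0.159 CPM, a log2 fold change of -2.61 ± 0.41 (DESeq2's adjusted p = 2.52e-05, edgeR's 0.0925, highest 0.615). In edgeR 0 of the 4 passed over all genes.

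T-lineage transcripts were high in control 1. Of 21 T-lineage genes outside the fixed lists, 19 were tested. Their median log2 ratio of control 1 over control 2 was 3.72 (95% bootstrap interval 2.18 to 4.89). The interval runs over genes and compares 1 library with 1, so it does not measure spread between samples. All 19 were higher in control 1, which thymus or other T-lineage tissue in that sample would give. Abundant ones included Satb1 (105, 55.2, 38.9 and 24.2 CPM in controls 1 and 2 and knockout-labelled libraries 1 and 2), Thy1 (63.0, 15.5, 15.8 and 32.7) and Coro1a (61.7, 8.97, 5.48 and 7.17), and 8 of the 19 reached 1 CPM in every other library too. No sort or gate was used. No biological explanation was tested, since the pattern lies within the control group.

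Camera placed the nuclear-encoded oxidative phosphorylation list higher in the knockout-labelled libraries (adjusted p = 9.13e-16; adjusted p = 0.657 with an estimated correlation). After removal of GC content and length trends it kept a median of 0.450 (95% bootstrap interval 0.36 to 0.50, over genes that vary together). The fitted trends thus did not account for all of the list's rise. Before removal its median of 0.66 lay above 100% of lists matched for GC content, length and level (matched median 0.31). Matched genes were drawn singly and need not vary together as these members do, so that percentile does not test the list. Without knockout-labelled 2 the list's median was 0.378 (0.322 to 0.437, over genes that vary together), so the rise was not confined to that library. With only knockout-labelled 1 left in its group, this value cannot tell a group difference from an offset of knockout-labelled 1. A larger share of cardiomyocyte RNA would raise sarcomere genes as much, and the list exceeded them by 0.395 (0.137 to 0.654), but by 0.12 (-0.10 to 0.45) after removal of GC content and length trends, so it remains open. Loss of Ctnnb1 or the Cre transgene also remains open, and batches are not given in the labels.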
